A study of Mus musculus with 2 samples.

How the data were processed

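Lung cells of 8 to 10 week old Lepr-Cre;Rosa26-tdTomato mice given saline or bleomycin were digested with collagenase, dispase and DNase, and live tdTomato-positive cells were sorted and put through droplet capture with the 3' v2 chemistry of 10x Genomics, with 1 library per group. The deposited matrices hold raw counts of UMIs per gene and barcode, with no normalization. Per the submitters' processing notes they were made with Cell Ranger 2.1.1 on the mm10 genome; the annotation release and the settings for calling cells are not given in the sources used here. Every value read was a whole number of at least 1. Both files list 28692 genes, of which 28339 (98.8%) match an identifier in GENCODE vM21, which was used for positions only. The saline library has 37570380 UMIs in 5455 barcodes and the bleomycin library 61537182 in 4473.

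Barcodes were kept as cells with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes, which left out 23 and 5. Doublets were scored with Scrublet in each library at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 10 and 4 barcodes, under the minimum of 0.5% set for trusting it, so the 238 and 160 barcodes with the highest scores, up to the expected rate, were left out. This left 5194 saline cells (median 6303.5 UMIs) and 4308 bleomycin cells (median 12276). Xist had 5 and 3 UMIs and the Y-linked Ddx3y 3654 and 3719.

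Counts were scaled per cell and log-transformed, 2000 variable genes chosen within each library were combined, and 30 principal components and 15 neighbours gave 26 Leiden clusters at resolution 1, with no integration of the libraries, so that a state found in 1 of them stayed apart. Clusters were named from fixed marker lists of 33 cell types: a name stands for a cell like that type throughout, as in fibroblast-like. A cluster took the lineage with the highest mean share of cells with its markers unless a second lineage reached 90% of it. At least 3 markers had to be found in 25% of the cells, and the 10 leading genes could hold no more markers of another lineage than of its own. A kind within a lineage needed a lead of 10 percentage points over the next. The marker lists were fixed before the data were examined, as were the gene lists, the size rule and the alternatives, but these naming thresholds were chosen after the clusters were seen. The leading genes against other lineages were Inmt, Clec3b and Mmp2 in cluster 0, Timp1 and Col1a1 in cluster 1, Ptn and Eln in cluster 2, Slc7a10 and Pcolce2 in cluster 3, Il6 and Tnfaip6 in cluster 4, Pi16 and Dcn in cluster 5, Mmp3 and S100a4 in cluster 6, Mfap4 and Figf in cluster 8, Ccl11 and Serpinf1 in cluster 15, and Saa3 and Cxcl10 in cluster 16. Chil3 and Ear2 led clusters 7, 11, 22 and 23.

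For all cells and for each class with at least 100 cells in each library, UMIs were summed per library and expressed per 1000000 UMIs of that class and library (UPM), and log2 ratios of bleomycin over saline were taken with a prior of 1 UPM. Intervals of levels are exact Poisson intervals, of ratios exact conditional binomial intervals, and of shares Clopper-Pearson intervals, all at 95%. With 1 library per group no test was made. A gene is said to have risen or fallen only past a size rule: at least 50 UMIs and at least 20 UPM in the higher library and at least a 2-fold ratio. A sum of 50 UMIs has an interval of 37.1 to 65.9. Where 1 library had 0 UMIs the fold is a bound, computed against 3 counts in that library. Each of 33 lists (504 genes) was summarised by the median log2 ratio of members with at least 20 UMIs, as a percentile among 10000 random lists of the same size matched on mean level, and called apart below 2.5 or above 97.5. The list genes Adrp and C1s are absent from the files under those names. The free-RNA floor of a gene is its lowest level among other lineages with at least 100 cells in the same library. After bleomycin only fibroblasts, immune cells and endothelial cells were that many. Expression by those lineages can raise the floor, so a gene that is not over it need not be free RNA.

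Genes were named by rule: the 10 highest and 10 lowest ratios past the size rule (5 and 5 outside all cells and the 3 largest classes, leaving out haemoglobin, sex-linked, mitochondrial, immunoglobulin, ribosomal and predicted genes), up to 4 members per list with the largest ratios, and 13 genes in every comparison, such as Lepr, Pdgfra, Col1a1 and Acta2. Of the genes this rule picked, 1 is not reported here. Shares of cells with a Lepr UMI were taken after thinning each cell to 2000 UMIs. The rules were tested on simulated data built from the saline cells: in fibroblasts 70 of 70 genes raised or lowered 2.5-fold were called and 0 of 5228 unchanged ones, and in endothelial cells 59 of 63 and 6 of 4341. Of random unchanged lists, 4.67% were called apart in simulated fibroblasts and 5.67% in endothelial cells. These simulated counts held Poisson error only, with no spread between cells or mice, so they give no rate of false calls between mice. For the clustering, 600 cells were simulated from summed profiles of alveolar fibroblasts, alveolar macrophages, endothelial and smooth muscle cells. Of these, 100.0% fell in a cluster of their own class. The 4 classes are far apart, and the parting of fibroblast kinds was not simulated.

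Alternatives tried were looser and stricter filters on barcodes, doublets kept, other cluster resolutions, each library clustered alone, equal weight per cell, scaling by the median of ratios, a prior of 10 UPM, thinning, and other minimum counts. Leaving out genes near the free-RNA floor, and leaving out endothelial and immune cells with over 0.2% of UMIs from 8 fibroblast markers, were chosen after seeing the data, as was taking general capillary cells alone for endothelial cells. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.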

Results

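The measurements were made on single lung cells of mice. The mice carried a Cre recombinase driven by Lepr, the leptin receptor gene, and a tdTomato reporter that Cre switches on for good. A sort for tdTomato thus aims at cells that had Lepr activity at some time, or whose forebears had. The purity of the sort was not tested, so a sorted cell need not have had such activity. The mice were 8 to 10 weeks old and had received saline or bleomycin, a DNA-damaging drug used to produce lung fibrosis in rodents. Live tdTomato-positive cells were sorted and their transcripts counted by droplet sequencing with unique molecular identifiers (UMIs), with 1 library per group. The saline library held 37570380 UMIs over 5455 barcodes (median 6353) and the bleomycin library 61537182 over 4473 (median 12389), and 5194 and 4308 barcodes were kept as cells. The number of mice behind each library, the dose and the day after treatment are not given in the sources used here. Without replicates no spread between animals can be stated and no test was made. Levels are sums over the cells of a class, as UMIs per 1000000 UMIs of that class (UPM), and a log2 ratio of UPM, bleomycin over saline, stands in parentheses after a gene. Square brackets hold exact 95% intervals, which cover counting error only.

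Fibroblasts made up most of the sorted cells in both libraries, immune cells came next, and epithelial cells were found almost only after saline. The comparison asks which cells passed the sort for the reporter from a normal and from a fibrotic lung. Fibroblasts were 71.4% [70.2 to 72.6] of 5194 saline cells and 82.6% [81.5 to 83.8] of 4308 bleomycin cells. Immune cells, mostly alveolar macrophages, were 13.8% [12.9 to 14.8] after saline and 9.61% [8.75 to 10.5] after bleomycin. Epithelial cells, among them alveolar type 2, ciliated and club cells, were 8.95% [8.19 to 9.76] (465 cells) after saline and 0.116% [0.0380 to 0.271] (5 cells) after bleomycin. Endothelial cells were 2.91% [2.47 to 3.40] and 4.29% [3.71 to 4.94], smooth muscle cells 1.98% [1.62 to 2.40] and 2.21% [1.79 to 2.69], and pericytes 0.943% [0.699 to 1.25] and 1.14% [0.843 to 1.501]. With each library clustered alone, the smooth muscle share was 3.49% after saline and no bleomycin cluster took that name. All shares are of cells that passed the sort for tdTomato, so they do not give the make-up of the lung.

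**Figure D1:**
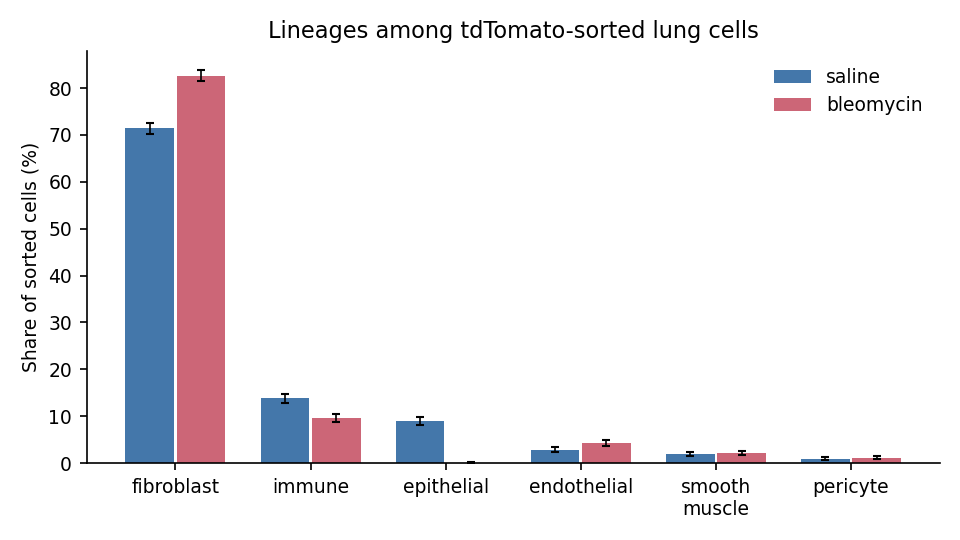
Share of sorted cells (y axis, percent) in each lineage (x axis) in the saline and bleomycin libraries; bars are shares and error bars exact 95% intervals for counting error. Fibroblasts were 71.4% after saline and 82.6% after bleomycin, and epithelial cells 8.95% and 0.116%.

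Endothelial and immune cells of some kinds from both libraries lay in shared clusters, which allows their numbers to be set side by side. Lymphatic endothelial cells were 0.366% [0.220 to 0.571] of saline cells and 1.63% [1.27 to 2.05] of bleomycin cells, and monocytes or interstitial macrophages 0.655% [0.454 to 0.914] and 1.70% [1.33 to 2.13]. General capillary endothelial cells were 2.04% [1.67 to 2.46] and 2.23% [1.81 to 2.72], and arterial endothelial cells 0.501% [0.327 to 0.733] and 0.441% [0.266 to 0.688]. Fibroblasts of the libraries parted into different clusters. Alveolar fibroblasts, marked by Npnt, Tcf21 and Inmt, came mostly from clusters 0, 3 and 4 after saline and cluster 8 after bleomycin, and adventitial fibroblasts, marked by Pi16 and Dpp4, mostly from cluster 5 after saline and cluster 15 after bleomycin. Clusters 1, 2, 6 and 16 met the rule for fibroblasts but for none of their kinds, and they held 2685 bleomycin and 154 saline cells. Cluster 16 went the other way from the rest, with 130 of those saline cells and 35 bleomycin cells. In clusters 1, 2 and 6 fibrotic fibroblast was the best kind but led the next by less than 10 percentage points. Cthrc1 was among the leading genes of each of them against other lineages.

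Lepr transcripts were scarcer in the bleomycin library, and most so in fibroblasts. The question was whether cells sorted for the Lepr reporter still carried Lepr mRNA. In all cells Lepr fell from 44.0 [41.9 to 46.3] to 7.21 [6.54 to 7.93] UPM (log2 ratio -2.46). In fibroblasts it fell from 44.6 [42.1 to 47.2] to 3.49 [2.999 to 4.03] (log2 ratio -3.35). Within alveolar fibroblasts the log2 ratio was -2.69, with 32.4 and 4.19 UPM, and within adventitial fibroblasts -2.27, with 111 and 22.1. Alveolar macrophages had 89.2 and 59.1 UPM of Lepr and endothelial cells 48.9 and 25.5, log2 ratios of -0.59 and -0.92 that were under the size required; the former passed it (-1.04) with each cell thinned to 2000 UMIs and the latter (-1.02) under the strict filter on barcodes.

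With every cell thinned to 2000 UMIs, 8.99% [8.23 to 9.80] of saline cells and 1.58% [1.23 to 2.00] of bleomycin cells held a Lepr UMI. The shares were 8.66% [7.77 to 9.61] and 0.702% [0.455 to 1.04] in fibroblasts, 5.87% [5.01 to 6.83] and 0.599% [0.0730 to 2.15] in alveolar fibroblasts, and 19.7% [16.9 to 22.8] and 4.81% [2.22 to 8.94] in adventitial fibroblasts. Alveolar macrophages gave 16.9% [14.1 to 20.04] and 6.93% [4.44 to 10.2], endothelial cells 11.9% [7.22 to 18.2] and 4.32% [1.89 to 8.34], and smooth muscle cells 6.80% [2.78 to 13.5] and 7.37% [3.01 to 14.6]. Saline epithelial cells, which served as background for free Lepr RNA, gave 0 of 465, which allows a share of cells with a Lepr UMI of up to 0.645% at 3 counts and up to 0.79% by the exact interval. Median depths before thinning were 5860.0 UMIs in those epithelial cells and 6737 and 13518 in saline and bleomycin fibroblasts. The interval of bleomycin fibroblasts spans both limits; the 5 bleomycin epithelial cells are too few for a limit of their own. Without thinning the shares were 22.4% and 6.89% in all cells and 23.7% and 3.96% in fibroblasts, and the background in saline epithelial cells was 1.72% [0.746 to 3.36] (8 of 465). Thinned to 1000 UMIs in a separate draw, 3 of 465 saline epithelial cells held a Lepr UMI.

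**Figure D2:**
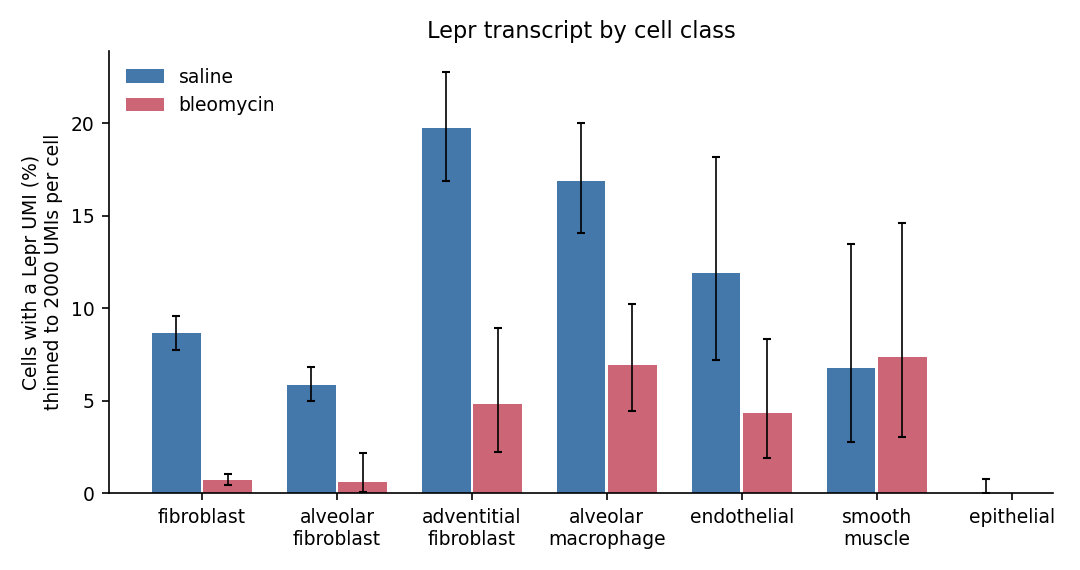
Share of cells with a Lepr UMI after thinning to 2000 UMIs per cell (y axis, percent) by cell class (x axis) in the saline and bleomycin libraries; bars are shares and error bars exact 95% intervals for counting error, and epithelial cells, drawn for saline alone, serve as background. The share was 8.66% in saline fibroblasts and 0.702% in bleomycin fibroblasts, and 0% in saline epithelial cells.

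Fibroblasts of the bleomycin library carried more mRNA for many matrix, myofibroblast and fibrotic genes, and less for alveolar fibroblast, complement and antigen presentation genes. The comparison asks how reporter-marked fibroblasts of a fibrotic lung differ from those of a normal one. Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 9.33 [8.20 to 10.6] to 4982 [4963 to 5001] UPM (log2 ratio 8.91), and Cthrc1, a secreted protein of fibrotic fibroblasts, rose from 1.33 [0.925 to 1.85] to 414 [409 to 419.9] (7.48). Col1a1, a chain of type I collagen, rose from 1447 [1433 to 1462] to 5437 [5417 to 5457] (1.91). Inmt, a methyltransferase abundant in alveolar fibroblasts, fell from 5009 [4982 to 5036] to 636 [629.6 to 643] (-2.97). In all, 344 genes rose and 545 fell past the size rule among 5881 with enough UMIs, over 3709 saline and 3560 bleomycin fibroblasts. Of these, 247 and 506 were at least 2 times their lowest level in another lineage, taken as the free-RNA floor. The pooled ratios mix changes within cells with different shares of fibroblast kinds. Alveolar fibroblasts were 2676 saline and 334 bleomycin cells, and adventitial fibroblasts 735 and 187.

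Besides Spp1 and Cthrc1, the named genes with the largest log2 ratios included Ctla2a (7.75), S100a4 (6.76), Hspb7 (5.86), Fst (5.83), Ptn (5.75) and Anxa8 (5.56). S100a4 is a calcium-binding protein, Hspb7 a small heat shock protein, Fst an activin-binding protein and Ptn the growth factor pleiotrophin. Postn, a matricellular protein, rose from 6.83 [5.87 to 7.90] to 437 [431 to 442] UPM (5.80). At the other end, Rbp4, the plasma carrier of retinol, fell from 378 [370.2 to 385] to 14.0 [13.01 to 15.1] (-4.66), and Colq, a collagen-like anchor of acetylcholinesterase, fell from 51.6 to 1.33 (-4.49). Cxcl5, a neutrophil chemokine, had a log2 ratio of -4.16 and was among the leading genes of cluster 16, with 130 saline and 35 bleomycin cells. Jchain, a plasma cell gene, had -6.56, but 47.9% of its UMIs in fibroblasts came from 1 cell, and with each library clustered alone it had -3.45 and missed the size rule. The other lowest ratios belonged to epithelial genes: Sftpc (-5.82), Sftpa1 (-5.71), Scgb1a1 (-5.39), Sftpb (-4.70), Cbr2 (-4.08) and Cxcl15 (-4.02). Whether their RNA in saline fibroblasts was free RNA was not tested.

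The matrix gene lists other than basement membrane had medians above random lists, with many of their members under the size rule. Of the fibrillar and associated collagens 8 of 14 measured members rose, 1 fell and 5 did neither, with a list median of 1.47 (log2) that was above random lists matched on expression. Among them were Col12a1, which rose from 21.1 to 142 UPM (2.70), and Col5a1, which rose from 70.2 to 373 (2.39). Col3a1 went from 2128 to 3541 with a log2 ratio of 0.73, under the size rule. Elastic fibre and matricellular proteins had a median of 0.66, and 9 of 23 measured members rose, 4 fell and 10 did neither, with Fbln2 (3.39) and Thbs2 (3.58) among the former. For collagen processing and crosslinking the median was 0.33 and 6 of 16 measured members rose, 1 fell and 9 did neither. The collagen crosslinking oxidases Lox and Loxl2 rose (1.71 and 2.52). Matrix proteases and inhibitors had a median of 0.45 and 6 of 19 measured members rose, 3 fell and 10 did neither, and Timp1, an inhibitor of matrix metalloproteinases, rose from 232 to 1149 (2.30), with Ctsk (1.77) and Mmp14 (1.52).

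Contractile genes had a median of 0.99, above random lists, and 7 of 15 measured members rose, 0 fell and 8 did neither. Acta2, the smooth muscle actin that marks myofibroblasts, rose from 194 [188 to 199] to 1437 [1427 to 1447] (2.89), with Des (2.43) and Tpm2 (2.49). The fibrotic fibroblast list had a median of 4.25, or 4.69 with its member at 0 UMIs at the floor of 3 counts, and 8 of 9 measured members rose, 0 fell and 1 did neither. Grem1, a BMP antagonist, rose from 1.10 [0.737 to 1.58] to 53.1 [51.2 to 55.1] (4.69). TGF-beta pathway genes and targets were not apart from random lists at 0.04, and 3 of 16 measured members rose, 1 fell and 12 did neither, with Inhba (2.87) and Ctgf (1.37) among the risen. Pdgfrb, the receptor for PDGF-BB, rose from 30.3 to 67.6 (1.13), and Pdgfra, the PDGF receptor common to most fibroblasts, had 461 and 252 (-0.87). The median of basement membrane genes was -0.11 and their mean 0.14, of opposite sign, and 2 of 15 measured members rose, 2 fell and 11 did neither.

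**Figure D3:**
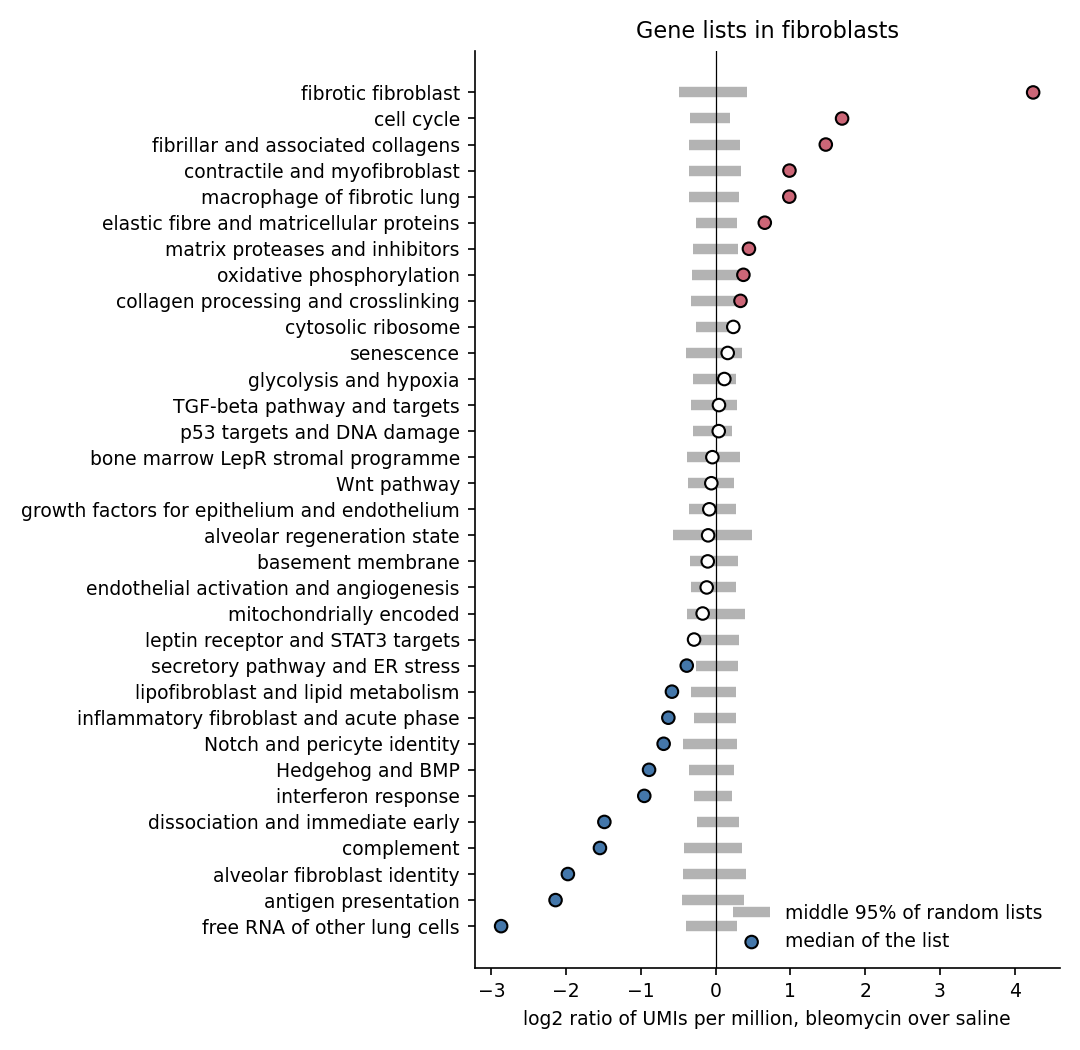
Median log2 ratio of UPM, bleomycin over saline, in fibroblasts (x axis) for the 33 gene lists (y axis); circles are list medians, filled where apart from random lists, and grey bars hold the middle 95% of 10000 random lists matched on size and expression. The fibrotic fibroblast list has the highest median, 4.25, and the list of free RNA of other lung cells the lowest, -2.87.

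Genes of normal alveolar fibroblasts were lower in the pooled fibroblasts. Alveolar fibroblasts were 2676 of 3709 saline and 334 of 3560 bleomycin fibroblasts. Within that class, which the identity genes themselves named, the median of the alveolar fibroblast identity list was -0.19. In the pooled fibroblasts 0 of 10 measured members of that list rose, 9 fell and 1 did neither, with a median of -1.98. Npnt, a matrix protein of the alveolar basement membrane, fell from 952 [940.0 to 964] to 211 [207 to 215] (-2.17), and the transcription factor Tcf21 fell from 342 [335 to 349] to 102 [99.1 to 105] (-1.74). Slc7a10, an amino acid transporter, had -3.61, and Fgfr4 -2.68. Lipofibroblast and lipid metabolism genes were below random lists at -0.59, where 3 of 18 measured members rose, 5 fell and 10 did neither, with Ces1d, a carboxylesterase, falling from 348 to 68.4 (-2.33). Pparg, a regulator of lipid genes, was near background with 4.17 and 2.29 UPM. Hedgehog and BMP genes were below random lists at -0.89, and 1 of 17 measured members rose, 6 fell and 10 did neither, among them Bmp3 (-2.44) and Ptch1, the Hedgehog receptor (-2.21). Notch and pericyte genes had a median of -0.70, where 1 of 13 measured members rose, 3 fell and 9 did neither, Heyl at -1.47 being one that fell. That median was 0.31 with each library clustered alone.

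Lists of immune genes were mostly lower in fibroblasts after bleomycin. Of the complement genes 0 of 12 measured members rose, 8 fell and 4 did neither, median -1.55, with C3, the central complement component, falling from 1093 [1080.3 to 1106] to 147 [144 to 150.5] (-2.88), and C1s1 (-2.37) and C4b (-1.66). Of the antigen presentation genes 0 of 10 measured members rose, 9 fell and 1 did neither, median -2.14, including Cd74 (-2.92) and H2-Aa (-2.66); the lowest levels of C3, Cd74 and H2-Aa in another saline lineage were 0.047, 0.216 and 0.261 times those in saline fibroblasts, and how much of the class II RNA came from other cells was not tested. Of the interferon response genes 1 of 23 measured members rose, 11 fell and 11 did neither, median -0.96, including Gbp2 (-2.34) and Cxcl9 (-2.07). Cxcl9 was among the leading genes of cluster 16, with 130 saline and 35 bleomycin cells. Inflammatory and acute phase genes had a median of -0.63, and 2 of 20 measured members rose, 7 fell and 11 did neither. The cytokine Il6, among the leading genes of cluster 4 (758 saline and 8 bleomycin cells), fell (-1.33). The protease inhibitor Serpina3n rose from 277 to 699 (1.33). All of these medians were below random lists. The list drawn up for macrophages of fibrotic lung was above them at 0.99, and 7 of 14 measured members rose, 2 fell and 5 did neither. Besides Spp1, fibroblasts had more of its members Lgals3 (3.55), which encodes galectin-3, and Gpnmb (2.14), and of S100a6 (2.39) from another list. What part of these levels is free RNA was not tested.

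Cell cycle genes were above random lists at 1.69, and 9 of 21 measured members rose, 0 fell and 12 did neither. Birc5 rose from 4.78 [3.98 to 5.69] to 38.4 [36.7 to 40.1] (2.77) and Ccna2 rose from 2.47 to 21.1 (2.67), but other lineages held comparable levels of both, 1.04 and 0.693 times those of bleomycin fibroblasts at their lowest. Within fibroblasts the cell cycle genes Hist1h2ap, Ube2c, Birc5 and Cdk1 led cluster 9, named fibrotic fibroblasts, which held 13 saline and 311 bleomycin cells; as such genes set the cluster apart, its size is no separate result. Mki67 had 2.24 and 9.13 UPM, under the size rule. Oxidative phosphorylation genes were above at 0.37 with 0 members past the size rule. Secretory pathway and ER stress genes were below at -0.39, and 0 of 22 measured members rose, 4 fell and 18 did neither, including Hspa5, the ER chaperone BiP, which fell from 821 to 376 (-1.13). Immediate early and dissociation genes were below at -1.49, and 0 of 24 measured members rose, 17 fell and 7 did neither. Fosb fell from 688 to 103 (-2.73) and Egr1 from 1359 to 289.6 (-2.23), both early-response transcription factors, with Nr4a1 (-2.30) and Atf3 (-2.04). Fosb, Egr1 and Nr4a1 were among the leading genes of cluster 4 within fibroblasts, which held 758 saline and 8 bleomycin cells. The free RNA list had a median of -2.87, and 0 of 15 measured members rose, 7 fell and 8 did neither.

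The remaining lists were not apart from random lists. The p53 target and DNA damage list had a median of 0.04 with 0 of 22 members past the size rule; Phlda3, a p53 target, had 211 and 358 UPM and Cdkn1a, the p21 gene, 368 and 352. Medians were 0.16 for senescence (1 rose and 2 fell of 12) and 0.12 for glycolysis and hypoxia (2 rose and 1 fell of 20), where Vegfa had -2.06. Leptin receptor and STAT3 targets gave -0.29 (1 rose and 4 fell of 14), with Socs3, a feedback inhibitor of STAT3, at -1.49. The bone marrow LepR stromal programme gave -0.04, with a mean of 0.20, of opposite sign (4 rose and 3 fell of 12); the transcription factor Ebf1 rose (2.37) and Angpt1, a ligand of the Tie2 receptor, fell (-1.41). Wnt pathway genes gave -0.06, with a mean of 0.32 and a median of 0.41 with each library clustered alone (2 rose and 3 fell of 19); the Wnt antagonist Sfrp1 rose from 115 to 362 (1.65). Growth factors for epithelium and endothelium gave -0.09 (1 rose and 4 fell of 16), with Ereg rising (3.52) and Fgf10 falling (-1.62). Endothelial activation genes gave -0.12, alveolar regeneration state -0.10, mitochondrially encoded genes -0.17 and cytosolic ribosome genes 0.24. With a prior of 10 UPM the protease (0.10), oxidative phosphorylation (0.34) and Notch (-0.13) medians were no longer apart from random lists and Pdgfrb had 0.95, and the fibrotic (2.29), cell cycle (0.88), lipid (-0.37) and free RNA (-0.84) medians kept their calls at smaller size; with each cell thinned to 2000 UMIs the protease (0.22) and oxidative phosphorylation (0.30) medians were not apart, the endothelial activation median (-0.69) lay below random lists and Ccna2 (2.14) missed the size rule, as it did with equal weight per cell (2.49). Medians that kept their call but moved were the contractile (0.65) and inflammatory (-0.35) ones with cells thinned, the inflammatory one (-0.42) with equal weight per cell, and the cell cycle one (2.70) with each library clustered alone.

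**Figure D4:**
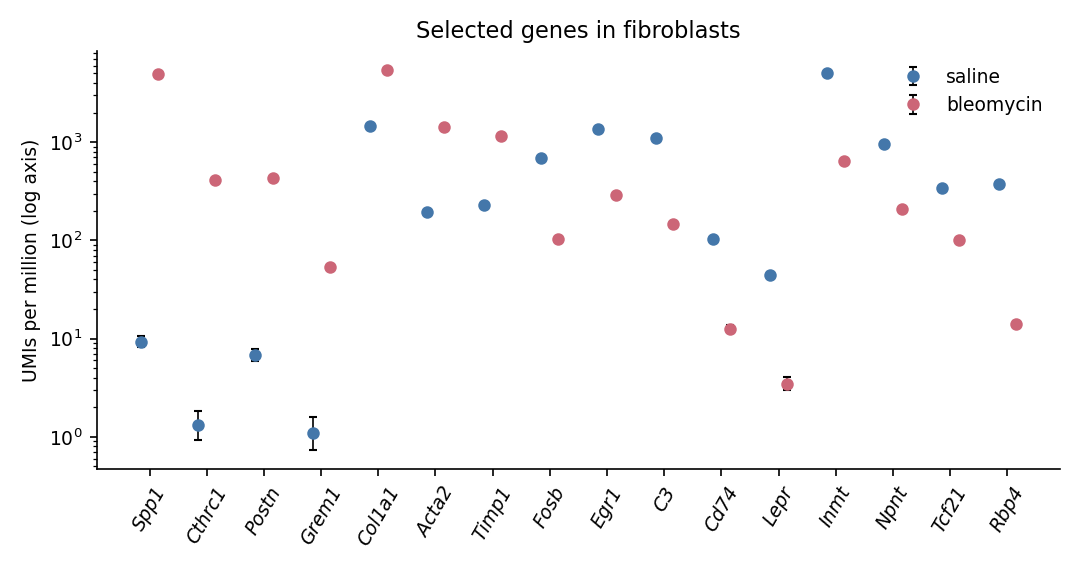
UPM (y axis, log axis) of 16 named genes (x axis) summed over fibroblasts of the saline and bleomycin libraries; points are single libraries and error bars exact 95% Poisson intervals, mostly smaller than the points. Spp1 stands at 9.33 after saline and 4982 after bleomycin, and Inmt at 5009 and 636.

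On the mm10 mouse genome these genes lie as follows by GENCODE vM21, with the identifiers given in the files. Lepr (ENSMUSG00000057722) lies on chromosome 4 from 101717404 to 101815352, Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050, and Cthrc1 (ENSMUSG00000054196) on chromosome 15 from 39076932 to 39087121. Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042, Acta2 (ENSMUSG00000035783) on chromosome 19 from 34241090 to 34255590, and Inmt (ENSMUSG00000003477) on chromosome 6 from 55170626 to 55175043. Spp1 overlaps the predicted gene Gm42793 on its own strand.

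Cells named alveolar fibroblasts after bleomycin had more mRNA for fibronectin, haptoglobin and the protease inhibitor Serpina3n and less for complement C3 and for antigen presentation and immediate early genes. Fn1, the gene of fibronectin, rose from 453 [443 to 462] to 1817 [1770.2 to 1865] UPM (2.00), and Serpina3n rose from 244 [237 to 251] to 834 [802 to 866] (1.77). Hp, of haptoglobin, rose from 151 [145 to 156] to 636 [609 to 665] (2.07). C3 fell from 963 [949.8 to 977] to 243 [226 to 261] (-1.98). The class was made of clusters 0, 3, 4 and 8, with 2676 saline cells, all but 32 of them outside cluster 8, and 334 bleomycin cells, 302 of them in cluster 8, and 81 genes rose and 215 fell, of which 62 and 180 stood over the free-RNA floor.

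The leading genes were Spp1 (6.20), Wfdc12 (4.45), Chodl (4.26), Hspb7 (3.12), Pla1a (2.28) and Wisp1 (2.12), a matricellular Wnt-induced protein, with Lrg1 (3.65), Ctla2a (3.63), S100a4 (2.94) and Fkbp5 (2.28). Spp1 at 187 UPM, Lrg1, Ctla2a, S100a4 and Fkbp5 were no higher than in the lineage that held least of them, so their level in these cells cannot be parted from free RNA. At the low end stood H2-Q7 (-4.02), Igfbp3 (-3.75), an IGF-binding protein that fell from 441 [432 to 450.1] to 31.9 [25.9 to 38.9], and C1qtnf3 (-3.45). Beside them were Jchain (-6.75, 49.1% of UMIs in 1 cell) and the epithelial genes Scgb1a1 (-5.68), Sftpa1 (-4.33), Sftpc (-4.15), Cbr2 (-4.06), Cxcl15 (-3.76) and Sftpb (-3.37). Jchain and Cxcl15 had 2 UMIs and Cbr2 1 after bleomycin, with ratio intervals of 0 to 0.0130, 0.00400 to 0.110 and 0 to 0.0860. Pdgfra had 511 and 594 UPM, Npnt 1199 and 998 and Tcf21 392 and 577, all under the size rule. Col1a1 had 1116 and 1044 and Col3a1 1849 and 1543.

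Of the elastic fibre and matricellular genes 5 of 22 measured members rose, 1 fell and 16 did neither, median 0.40, above random lists; Tnc, of tenascin C, had 1.90 and decorin, Dcn, was the member that fell (-3.17). The fibrotic list, 2.19, was above as well (3 rose and 0 fell of 6), as was the contractile list, 0.42, with 0 members past the size rule. Fibrillar and associated collagens, at -0.10, and the identity list, at -0.19, were not apart at the settings used. Of the identity list 1 of 10 members, Figf, a vascular growth factor, rose (1.05). The same 10 genes named the class, and clusters low in them could not take the name. A small change of the identity list was thus partly built in. Of the antigen presentation genes 0 of 10 measured members rose, 7 fell and 3 did neither, median -1.66, with H2-K1 (-2.39) and H2-D1 (-1.85). Of the complement genes 0 of 11 measured members rose, 4 fell and 7 did neither, median -0.90, with C2 (-1.92) besides C3. Interferon genes were below at -0.60 (0 rose and 8 fell of 21), with Gbp2 (-2.20) and Cxcl10 (-1.71). Immediate early genes were below at -1.20 (0 rose and 16 fell of 24), with Klf4 (-2.68) and Fosb (-2.15). Fosb was among the leading genes of cluster 4 within fibroblasts, with 758 saline and 8 bleomycin cells. Inflammatory and acute phase genes were below at -0.90, or -0.55 with the member at 0 UMIs at its floor, and 2 rose and 4 fell of 19: Hp and Serpina3n rose and Ccl2, a monocyte chemokine, fell (-2.54).

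The class was small after bleomycin and its edge moved with the settings. With a finer clustering (resolution 2) 242 genes rose and the collagen median was 0.80 and the inflammatory one 0.67, both of opposite sign, with Col1a1 at 1.06; scaling by the median of ratios shifted all genes by 0.104, and 50 rather than 81 genes then rose, 16.0% rather than 27.4% of those past the size rule. The changes of Dcn (-0.09), Figf (0.50), Ccl2 (-0.43), C2 (-0.98) and Cxcl10 (-0.69) no longer met the size rule at that resolution, while Npnt (-1.26) met it and the identity median, -1.06, lay below random lists. The strict filter gave Npnt -1.27, an identity median of -1.08 and Dcn -0.11, and each library clustered alone -1.06, -0.86 and -0.81. Under the strict filter Ccl2 (-0.57) and Cxcl10 (-0.76) missed the size rule too. The identity median was also called below random lists with doublets kept (-0.25), with the loose filter (-0.24) and with cells thinned (-0.24). The complement median was -0.20 at resolution 2 and -0.28 under the strict filter, neither apart from random lists. Figf missed the size rule under 6 alternatives (0.47 to 0.95) and C1qtnf3 and Jchain under 5, and with each cell thinned to 2000 UMIs Wfdc12, Chodl, Hspb7, Pla1a, Wisp1, Lrg1, S100a4, Fkbp5 and Cxcl15 missed its minimum of UMIs or UPM. With lists kept on the same side of random lists, medians moved to 1.06 (matricellular), 1.12 (contractile), -1.05 (antigen presentation) and -0.31 (interferon) at resolution 2, and with a prior of 10 UPM to 1.16 (fibrotic), 0.25 (matricellular) and -0.36 (inflammatory).

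In adventitial fibroblasts, which surround airways and vessels, the lists of collagens, matricellular proteins and inflammatory genes were above random lists after bleomycin and the Hedgehog and BMP list below. Col1a1 rose from 2813 [2764 to 2864] to 6954 [6832 to 7079] UPM (1.31) and Col3a1 from 3097 [3045 to 3150.2] to 7069 [6945 to 7194] (1.19). Serpina3n rose from 343 [325 to 360.4] to 1932 [1867 to 1998] (2.49). Wnt4, a Wnt ligand, fell from 155 [144 to 167] to 4.54 [1.96 to 8.94] (-4.82). The class was made of clusters 5 and 15, with 735 saline cells, 724 of them in cluster 5, and 187 bleomycin cells, 158 of them in cluster 15, and 143 genes rose and 380 fell, of which 118 and 333 stood over the free-RNA floor.

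The genes with the highest ratios were Ctla2a (7.35), Cthrc1 (6.97) and A2m, the protease inhibitor alpha-2-macroglobulin (4.76), with Lrg1 (6.60) and Spp1 (6.42) not over the free-RNA floor. Lrg1 and Spp1 were among the leading genes of macrophage cluster 11 within immune cells. Their floor may therefore hold expression as well as free RNA. Cthrc1 had 3 UMIs after saline, with a ratio interval of 103 to 1482, and A2m and Lrg1 had 1, with 24.1 to 5605 and 90.8 to 20298. Shisa2 had 87 UMIs after saline and 0 after bleomycin, at least 11.9-fold lower. The epithelial genes Sftpc (-5.92), Sftpa1 (-5.56), with 1 UMI after bleomycin and a ratio interval of 0 to 0.0440, and Scgb1a1 (-5.18) completed the low end. Of the fibrillar and associated collagens 7 of 14 measured members rose, 0 fell and 7 did neither, median 0.96. Of the elastic fibre and matricellular genes 9 of 23 measured members rose, 3 fell and 11 did neither, median 0.61, among them Tnc (3.36), Postn (2.94) and Fn1 (2.56). The fibrotic list had 3.36 (5 rose and 0 fell of 7), or 2.13 with a prior of 10 UPM. Timp1 rose from 215 to 1339.6 (2.63).

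Of the inflammatory and acute phase genes 8 of 20 measured members rose, 0 fell and 12 did neither, median 0.66, above random lists. They included Ptx3 (3.84), a pattern recognition protein, Cxcl13 (3.24), a B cell chemokine, and Ccl7 (2.67), of whose UMIs 46.8% came from 1 cell. Below random lists were antigen presentation, -1.42 (0 rose and 5 fell of 9), with H2-Ab1 (-2.44); interferon response, -0.50 (4 rose and 8 fell of 21), with Cxcl10 (-2.58); and immediate early genes, -1.11 (0 rose and 17 fell of 24), with Fosb (-2.08). Hedgehog and BMP genes were below as well at -0.67, and 0 of 15 measured members rose, 6 fell and 9 did neither; Ptch1 fell from 242 [227 to 257] to 51.0 [41.0 to 62.7] (-2.22) and the Hedgehog effector Gli1 from 46.6 to 13.6 (-1.70). Tcf21 fell (-1.17) and Pdgfra had 349 and 232 UPM. With each cell thinned to 2000 UMIs, which leaves fewer UMIs in a small class, A2m, Postn, Ptx3, Tnc and H2-Ab1 had 14, 44, 17, 16 and 44 UMIs in the higher library, under the minimum, Tcf21 had -0.85, and the interferon median of -0.12 was not apart from random lists, as it was not at -0.31 with equal weight per cell. Shisa2, at 20.2 UPM after saline, was near the minimum of 20 UPM and missed the size rule at both other resolutions, with doublets kept, under both other filters, with equal weight per cell, with cells thinned and with a minimum of 200 UMIs.

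Alveolar macrophages had more mRNA for osteopontin and cathepsin K after bleomycin and less for the scavenger receptor Cd36. Spp1 rose from 351 [329 to 373] to 3516 [3440.2 to 3593] UPM (3.32). The C1q chain C1qb rose from 5.47 [3.13 to 8.88] to 120.3 [107 to 135] (4.23), with C1qc (3.81) and C1qa (3.79). These genes also led cluster 18, the monocytes or interstitial macrophages, which were 0.655% of saline and 1.70% of bleomycin cells. At resolution 2 C1qc had 10 UMIs after saline and 28 after bleomycin, against 10 and 142 at the settings used. Most of the C1qc rise thus lay in cells that were not in this class at that resolution. Ctsk, a collagen-degrading protease, rose from 318 [298 to 339.6] to 1025 [985 to 1067] (1.68). Cd36 fell from 219 [202 to 237] to 62.1 [52.4 to 73.0] (-1.80). The class was made of clusters 7, 11, 22 and 23, with 639 saline cells, 556 of them in cluster 7, and 332 bleomycin cells, 305 of them in cluster 11; 147 genes rose and 259 fell, and 94 and 181 stood over the free-RNA floor. Among immune cells as a whole, 717 and 414 cells, 149 rose and 278 fell.

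Ear10, an eosinophil-associated ribonuclease, had 0 UMIs after saline and 69.3 UPM after bleomycin, at least 67.6-fold higher. Apoc4, with 1 UMI after saline, had a ratio interval of 11.0 to 2572 (4.09), and Lrg1 rose from 18.8 to 175 (3.15). Ctla2a (4.89), Cthrc1 (3.96) and Col1a1 (1.71) were also higher, at less than 2 times their lowest level in another lineage, and Cthrc1 had 2 UMIs after saline, with a ratio interval of 9.79 to 312. Fbp1, a gluconeogenic enzyme, had 77.6 UPM after saline and 0 after bleomycin, at least 60.4-fold lower. Rnase2a (-5.59) had 1 UMI after bleomycin, with a ratio interval of 0 to 0.0350. Mmp12, the macrophage elastase, fell from 189 to 36.4 (-2.35), and Krt19 from 352 to 96.3 (-1.86). Fbp1, Rnase2a and Mmp12 were among the leading genes of cluster 22, with 48 saline and 0 bleomycin cells. Sftpa1, at least 123-fold lower with 0 UMIs after bleomycin, Sftpc (-6.91) and Scgb1a1 (-6.25) are epithelial genes. Sftpc and Scgb1a1 were among the leading genes of cluster 7 within immune cells, with 556 saline and 9 bleomycin cells. Whether their RNA in macrophages was free RNA was not tested.

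In the list for macrophages of fibrotic lung 9 of 14 measured members rose, 1 fell and 4 did neither, median 1.49, above random lists; Arg1, arginase 1, rose (2.29) with 48.2% of its UMIs in 1 cell. The complement list had a median of -0.54, below random lists, and a mean of 0.47, of opposite sign, where 3 of 11 measured members rose, 3 fell and 5 did neither; the C1q genes were those that rose, and the median was 0.05 over members with at least 100 UMIs. Antigen presentation genes were below at -0.88, and 0 of 9 measured members rose, 2 fell and 7 did neither, H2-Aa falling from 1066 to 530.3 (-1.01). Immediate early genes were below at -0.76 (0 rose and 7 fell of 24), with Egr1 (-1.65). Pparg, which alveolar macrophages need for their identity, had 119.6 and 94.6 UPM, and Mki67 20.5 and 24.0. With each library clustered alone C1qa (2.38) and C1qc (2.31) had 49 and 34 UMIs after bleomycin, Mmp12 had -0.34, and UMIs after saline and bleomycin were 0 and 14 for Ear10, 0 and 39 for Arg1, 1 and 1 for Apoc4, 36 and 0 for Fbp1 and 19 and 0 for Rnase2a, so that none of these met the size rule. At resolution 2 neither did C1qa (1.05), C1qc (1.60), Arg1 (1.84), Ear10 (0 and 34 UMIs) and Apoc4 (1 and 1), and with cells thinned neither did Apoc4, Arg1 and Cthrc1, nor was the complement median (-0.44) apart. H2-Aa lay at the edge of the size rule and missed it under 7 alternatives, at -0.998 to -0.797.

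Endothelial cells had less mRNA for antigen presentation and interferon genes after bleomycin and more for cell cycle genes, by an amount that depended on the clustering. Of the cell cycle genes 16 of 21 measured members rose, 0 fell and 5 did neither, median 3.27, also with members at 0 UMIs at their floor. Cdk1, the mitotic kinase, had 0 UMIs after saline and 79.7 UPM after bleomycin, at least 31.5-fold higher. Lrg1, a glycoprotein linked to vessel growth, rose from 327 [296 to 362] to 1674 [1616 to 1733] UPM (2.35). Cd74, the invariant chain of class II molecules, fell from 1952 [1873 to 2033] to 372 [345 to 400.3] (-2.39). In all 461 genes rose and 495 fell over 151 and 185 cells from shared clusters 12, 20 and 24, of which 339 and 461 stood over the free-RNA floor. The kinds differed in number: lymphatic cells were 19 of the 151 and 70 of the 185, and general capillary cells 106 and 96.

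Other leading genes were Ube2c, a mitotic ubiquitin enzyme (6.11), and the histone gene Hist1h2ap (5.85), with 2 and 1 UMIs after saline and ratio intervals of 30.0 to 905 and 22.2 to 4971. Fhl2 had 0 UMIs after saline and was at least 21.8-fold higher, and Serinc2 (5.75) had 1, with a ratio interval of 20.6 to 4623. Mki67, at 0 UMIs after saline and 25.0 UPM after bleomycin, was under the size rule. Activation genes were not apart from random lists at 0.00 and 4 of 19 measured members rose, 1 fell and 14 did neither, with Angpt2, a Tie2 ligand, rising from 15.2 to 80.2 (2.33) beside Ackr1 (1.87) and Ackr3 (1.59). The chemokine Ccl2 rose (2.82), as did Ptx3 (3.47) and the basement membrane collagen gene Col18a1 (1.74). Glycolysis and hypoxia genes were above at 0.59 (4 rose and 2 fell of 20), with Eno1, enolase, rising (1.65), and oxidative phosphorylation genes at 0.49 (2 rose and 0 fell of 16). Of the antigen presentation genes 0 of 10 measured members rose, 9 fell and 1 did neither, median -1.28, with H2-Eb1 (-2.62) besides Cd74. Interferon genes were below at -1.42 (0 rose and 11 fell of 20), and immediate early genes at -1.14 (0 rose and 16 fell of 23), with Egr1 (-2.20). With each cell thinned to 2000 UMIs Angpt2, Ccl2, Cdk1, Fhl2, Hist1h2ap and Serinc2 had fewer than 50 UMIs. The glycolysis median was 0.28 and not apart from random lists at that depth, and the oxidative phosphorylation median 0.39 and not apart at resolution 2. The activation median lay below random lists at resolution 2 (-0.62), without cells that carried fibroblast RNA (-0.52) and over members with at least 100 UMIs (-0.37).

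With general capillary cells alone, an alternative chosen after seeing the data, 170 rather than 461 genes rose. Angpt2 (0.38), Col18a1 (0.25) and Eno1 (0.33) then missed the size rule, as did Ccl2 with 30 UMIs after saline and 3 after bleomycin, Cdk1 with 0 and 19, Hist1h2ap with 0 and 43, Ube2c with 1 and 40, and Ptx3, Fhl2 and Serinc2 with 0 and 1 each. The cell cycle median was then 1.35, still above random lists, the activation median 0.63 and above them, and the glycolysis (0.28) and oxidative phosphorylation (0.33) medians not apart. Antigen presentation (-1.15), interferon (-1.29) and immediate early genes (-0.35) stayed below random lists, as Cd74 (-1.60) stayed lower, and Lrg1 (3.14) higher, past the size rule.

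Fibroblast genes were among the lowest in endothelial cells: Inmt (-5.73), Dpep1 (-5.70), Pcolce2 (-5.66), Tcf21 (-5.57) and Pdgfra (-4.08). Beside them were the epithelial genes Sftpc (-6.53) and Sftpa1 (-5.86), the last with 1 UMI after bleomycin and a ratio interval of 0 to 0.0340. The saline endothelial cells carried fibroblast RNA: 49 of 151 (32.5%) had over 0.2% of their UMIs from 8 fibroblast markers, against 3 of 185 (1.62%) after bleomycin. Without those cells 265 rather than 495 genes fell, the collagen list went from -1.08 to 0.31 and Col1a1 from -0.98 to 2.43. The lower collagen median thus rests on them. Col1a1, Col1a2 and Col3a1 are among the 8 markers, however, so part of this rise was built into the choice of cells. Inmt stayed lower, at -3.14 and past the size rule, and Dpep1, Tcf21, Pcolce2 and Pdgfra had 11, 6, 29 and 12 UMIs left after saline and 3, 1, 15 and 14 after bleomycin, too few for it. Col1a1 met the size rule with general capillary cells alone (-1.42) and with each library clustered alone (-1.36). The cell cycle list stayed above random lists under every alternative, but its size moved with the clustering: with each library clustered alone the median was 0.54 and the log2 ratios of Cdk1 and Ube2c 0.28 and 0.31, under the size rule, and the median was 1.54 with each cell thinned to 2000 UMIs and 2.05 with a prior of 10 UPM.

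Over all sorted cells pooled, fibrotic genes were higher after bleomycin, and the named genes that fell furthest were genes of epithelial cells. Spp1 rose from 41.3 [39.2 to 43.5] to 4694 [4676 to 4711] UPM (6.79) and Cthrc1 from 2.73 [2.21 to 3.34] to 373 [368 to 378] (6.65), followed by genes that included S100a4 (5.90), Ptn (5.60), Fst (5.15), Ctla2a (5.13), Hspb7 (4.83), Grem1 (4.74) and Adam12 (4.25), the last short of the size rule with cells thinned and with equal weight per cell. Sftpc, the gene of surfactant protein C, fell from 11673 [11637 to 11708] to 52.3 [50.5 to 54.2] (-7.77), with Sftpa1 (-9.46), Scgb1a1 (-8.87), the club cell secretoglobin, Sftpb (-7.08), Cxcl15 (-6.91), Scgb3a2 (-6.91), Retnla (-6.64), Sftpd (-6.59), Scgb3a1 (-6.33) and Slc34a2 (-6.25). In all 291 genes rose and 549 fell, among 6049 with enough UMIs. Col1a1 rose from 1116 to 4891 (2.13), Acta2 from 533 to 1503 and Postn from 25.7 to 408 (3.93). These ratios mix changes within cells with the different shares of cell types, since epithelial cells were 8.95% of saline and 0.116% of bleomycin cells.

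Msln, which encodes mesothelin and is best known from mesothelial cells, was singled out after its values were seen. It had 1 UMI in saline fibroblasts and 1576 in bleomycin fibroblasts, 0.038 and 30.0 UPM (log2 ratio 4.90, ratio interval 142 to 31277). After thinning, 0 of 3709 saline fibroblasts and 2.70% [2.19 to 3.28] of bleomycin fibroblasts held a Msln UMI, against 0 of 334 bleomycin alveolar fibroblasts, which allows up to 0.898% at 3 counts and up to 1.10% by the exact interval, 1.62% [0.336 to 4.67] of endothelial cells and 0.725% [0.150 to 2.103] of immune cells. Bleomycin cells other than fibroblasts had 14 Msln UMIs, 2.26 UPM [1.23 to 3.79]. Cluster 6, with 658 bleomycin cells, held 82.6% of the Msln UMIs of bleomycin fibroblasts. The same cluster had 83027 UMIs of Col1a1 (6938 UPM). It had 0 UMIs of Upk3b and of Lrrn4 and 3 of Wt1, other genes of mesothelial cells, and 1628 of Upk1b, of which saline fibroblasts had 2635. Msln (ENSMUSG00000063011) lies on chromosome 17 from 25748613 to 25754378.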

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

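All tests of explanations in this part were chosen only after the results were seen. The lists of the first paragraph are those that lay above random lists in 1 and below them in another of 4 classes with no cells in common, alveolar and adventitial fibroblasts, alveolar macrophages and endothelial cells; differences between classes were not tested.

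The alveolar regeneration state list had medians of -0.71 (percentile 0.71) in alveolar fibroblasts, -0.64 (0.81) in alveolar macrophages and 0.90 (99.8) in adventitial fibroblasts. It was no longer apart from random lists in alveolar fibroblasts at resolution 2 (-0.22), with doublets kept (-0.33), with each library clustered alone (-0.13), under the strict filter (-0.10), with each cell thinned to 2000 UMIs (-0.50) and over members with at least 100 UMIs (-0.37), nor in alveolar macrophages under the last pair (-0.52 and -0.33). The cytosolic ribosome list had -0.32 (2.495) in alveolar macrophages and 0.34 (99.7) in adventitial fibroblasts, and the former was not apart with cells thinned (-0.34), over members with at least 100 UMIs (-0.32), with equal weight per cell (-0.32) and with scaling by the median of ratios (-0.27). Fibrillar and associated collagens had 1.12 (100) in alveolar macrophages, 0.96 (100) in adventitial fibroblasts and -1.08 (0) in endothelial cells. In the macrophages Col1a1 was at less than 2 times its free-RNA floor. The endothelial median was 0.31 without endothelial cells that carried fibroblast RNA, and not apart at resolution 2 (-0.06) and with doublets kept (-0.16). Glycolysis and hypoxia genes had -0.26 (0.44) in alveolar fibroblasts and 0.59 (99.99) in endothelial cells, neither apart with cells thinned (-0.21 and 0.28). Inflammatory and acute phase genes had -0.90 (0) in alveolar fibroblasts, -0.63 (0.02) in alveolar macrophages and 0.66 (100) in adventitial fibroblasts, and in alveolar fibroblasts 0.67 at resolution 2, 0.66 under the strict filter and 0.19 with each library clustered alone.

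Fibroblasts of the bleomycin library had 3.49 UPM of Lepr against 44.6 after saline. Dilution by a few abundant genes would lower all genes alike, but the median log2 ratio of all genes with at least 100 UMIs in each library was -0.074. A loss of adventitial fibroblasts alone would leave Lepr unchanged within each kind, but the upper bounds of its ratio within alveolar and adventitial fibroblasts reached at most 0.277. These kinds held only 334 and 187 of the 3560 bleomycin fibroblasts, mostly from other clusters than after saline. Other changes in which cells make up the fibroblasts, or a kind of them, were not tested. Free Lepr RNA in the saline library would reach epithelial cells, where the exact upper bound of the share with a Lepr UMI was 0.79% against a lower bound of 7.77% in fibroblasts, or 3.36% against 22.3% without thinning. A lower Lepr mRNA level in reporter-marked fibroblasts after bleomycin may remain as an untested hypothesis, beside differences between the mice behind these 2 libraries.

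Immediate early and dissociation genes were lower after bleomycin. A gap in depth per cell argues for little of it, as the fibroblast median was -1.44 with every cell thinned to 2000 UMIs. The list was below random lists in 4 of 4 separate classes, alveolar and adventitial fibroblasts, alveolar macrophages and endothelial cells, which is consistent with handling that differed between the libraries. With general capillary cells alone the endothelial median was smaller in size, though still below random lists. Within fibroblasts Fosb, Egr1 and Nr4a1 were among the leading genes of cluster 4, with 758 saline and 8 bleomycin cells. The count of classes thus does not part handling from a different mix of cells within them. A response of the lung to bleomycin that reached all 4 classes stays open and was not tested.

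Msln was found in bleomycin fibroblasts and almost never in saline ones. Mesothelial cells would bring their other abundant transcripts, but UMIs of Upk3b, Lrrn4 and Wt1 together were 0.23% of the Msln UMIs in cluster 6, and Rspo1 and Gpm6a had 1 UMI each; Upk1b, with 1628 UMIs (136 UPM), decides nothing here, as saline fibroblasts with 1 Msln UMI in all held it at 99.97 UPM. Free Msln RNA would reach all cells of that library alike, but the exact upper bound of the share with a Msln UMI in alveolar fibroblasts was 1.10% against 2.70% [2.19 to 3.28] in all fibroblasts, and cells other than fibroblasts had 2.26 UPM [1.23 to 3.79] against 30.0 [28.6 to 31.5], though the share in endothelial cells, 1.62% [0.336 to 4.67], does not by itself part them from fibroblasts. Fibroblasts that express Msln after bleomycin may therefore be a hypothesis to follow up, with other sources untested.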

How the results depend on the processing

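The alternatives that left out genes near the free-RNA floor, or endothelial and immune cells with fibroblast RNA, or that took general capillary cells alone for endothelial cells, were the only ones chosen after seeing the data. Leaving out a replicate was impossible with 1 library per group. No paired analysis was possible because nothing in the labels pairs the libraries. Of 2592 recomputed log2 ratios of named genes, 2450 kept their side of the size rule, 127 lost the size rule and 10 gained it. A further 5 changed sign where the settings used or the alternative met the rule. Of 785 recomputed list medians, 735 kept their call, 29 lost it and 8 gained it. A further 13 changed sign where the settings used or the alternative were apart from random lists. Changes of sign among ratios and medians called at neither setting were not counted. The senescence median in fibroblasts, for example, ranged from -0.035 to 0.235. Cells kept ranged from 5011 to 5432 after saline and from 4235 to 4468 after bleomycin. In fibroblasts the collagen median stayed between 1.39 and 1.55 over all alternatives, the alveolar identity median between -2.00 and -1.67 and the immediate early median between -1.50 and -1.42. Depth limits the smaller classes most: counts of genes in endothelial cells, alveolar macrophages and both kinds of fibroblast follow the minimum count. Where a change does not follow from the way the alternative is built, its cause was not tested.

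With no minimum count, which lets in genes with few UMIs, 637 genes were higher and 1536 lower in all cells, 828 and 1072 in fibroblasts, 247 and 724 in alveolar fibroblasts, 703 and 1123 in adventitial fibroblasts, 501 and 1157 in immune cells, 522 and 1229 in alveolar macrophages, and 1639 and 1939 in endothelial cells. With at least 200 UMIs, 57 were higher and 222 lower in adventitial fibroblasts, 61 and 109 in alveolar macrophages, 76 and 134 in immune cells and 150 and 160 in endothelial cells, and 38 were higher in alveolar fibroblasts. With each cell thinned to 2000 UMIs, 62 were higher in adventitial fibroblasts, 37 in alveolar fibroblasts, 76 in alveolar macrophages, 99 in immune cells and 100 in endothelial cells, where 130 were lower, and 7 lists were below in alveolar macrophages. With a prior of 10 UPM, 41 genes were higher in alveolar fibroblasts and 89 in alveolar macrophages, and 227 were lower in adventitial fibroblasts, 166 in alveolar macrophages and 173 in immune cells. Median of ratios scaling gave 50 higher genes in alveolar fibroblasts. Without genes at less than 2 times the lowest level in another lineage, 94 were higher in alveolar macrophages. With equal weight per cell 7 lists were below in immune cells. Over list members with at least 100 UMIs, 3 lists were above in alveolar macrophages, the complement median there was 0.05, and the endothelial activation median in endothelial cells -0.37.

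At resolution 2, alveolar fibroblasts had 242 higher genes, 10 lists above and 8 below, Col1a1 at 1.06, collagens at 0.80 and inflammatory genes at 0.67. Endothelial cells then had 282 lower genes, Col1a1 at 2.02 and an activation median of -0.62, and were 2.00% of saline cells. Under the strict filter alveolar fibroblasts had 247 higher genes, 10 lists above and 8 below, Col1a1 at 1.09, collagens at 0.80 and inflammatory genes at 0.66. Epithelial cells were then 6.85% and fibroblasts 73.4% of saline cells. With each library clustered alone, alveolar fibroblasts had 203 higher genes, 7 lists above, collagens at 0.58 and inflammatory genes at 0.19. In fibroblasts the Notch median was then 0.31 and the Wnt median 0.41. Fibroblasts were then 69.4% and smooth muscle cells 3.49% of saline cells, and both epithelial and smooth muscle cells 0% of bleomycin cells, 97 of which (2.25%) took no name. Without cells that carried fibroblast RNA, endothelial cells had 265 lower genes, Col1a1 at 2.43, collagens at 0.31 and an activation median of -0.52. With general capillary cells alone, which leaves fewer UMIs, endothelial cells had 170 higher genes, Ccl2 at -2.89 (30 and 3 UMIs, under the size rule) and an activation median of 0.63.

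Without thinning, shares with a Lepr UMI were 22.4% after saline and 6.89% after bleomycin in all cells, and 23.7% and 3.96% in fibroblasts. With cells thinned to 1000 UMIs they were 4.81% and 0.905% in all cells, and 4.61% and 0.365% in fibroblasts.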

Other observations

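Smooth muscle cells and pericytes, each in a cluster shared by both libraries, were too few for a comparison of genes. After thinning to 2000 UMIs, 7 of 103 saline and 7 of 95 bleomycin smooth muscle cells held a Lepr UMI, and 8 of 49 and 4 of 49 pericytes. Their median depths were 5420.0 and 7470.0 UMIs for smooth muscle and 4517 and 7382 for pericytes.

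Spp1, the osteopontin gene, was spread widely in the bleomycin library. After thinning, an Spp1 UMI was found in 89.2% of bleomycin alveolar macrophages, 73.5% [58.9 to 85.1] of 49 pericytes, 51.3% of fibroblasts, 33.5% of endothelial cells and 30.5% of smooth muscle cells, with median depths of 6714, 7382, 13518, 7555 and 7470.0 UMIs. What part of these shares is free Spp1 RNA was not tested. After saline the shares were 32.9% in alveolar macrophages, 12.2% in pericytes, 0.62% in fibroblasts, and 0 of 151 in endothelial and 0 of 103 in smooth muscle cells, which allows up to 1.99% and 2.91% at 3 counts.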
